A study of Escherichia coli K-12 with 3 samples.

How the data were processed

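Total RNA of 3 Escherichia coli K-12 mutants and of wild type was labelled directly with Alexa555 or Alexa647 dUTP during cDNA synthesis, and each mutant was co-hybridised with wild type on oligonucleotide arrays with reverse dye labelling, per the labels. Per the file headers, the raw table deposited by the authors holds the raw mean intensity of each spot, in 1 column for wild type and 1 column for each mutant. The sources used here do not say whether the mean runs over pixels, arrays or dye orientations, nor which scanner, software or background treatment was used. The deposited value table holds the natural log of wild type over mutant. This was found from the values, since for 3766 probes between 97.9% and 98% of the entries of each column lay within 0.001 of the natural log of the ratio of mean raw intensities, with no centring and no normalization. Its column medians were 0.105, -0.315 and -0.348 for the ppk-, ppx- and double-labelled samples.

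The raw table had 8444 spot rows, 2 spots for each of 4222 probes, and 4141 gene symbols. Of these genes, 80 had more than 1 probe, and all spots of a gene were averaged. Of 79 genes with 2 probes, 3 in the ppx-labelled and 3 in the double-labelled sample had a probe past 2-fold, and in none were both probes past it in the same direction. ECK codes were matched for 4133 genes (99.8%) to the RefSeq annotation of assembly ASM584v2, which was used only for current names and for which genes neighbour each other. The current symbol differed for 624 genes. A wild-type spot of sbmA, at 47752875, lay above the range of a scanner (65535) and was left out, and the other spot of sbmA was kept. No filter on dim spots was applied.

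Before the data were examined, the plan was to normalize by loess where a column was given for each array and channel, and to take the deposited value on the log2 scale where only 1 value per mutant was given. The files fit neither case exactly, since they hold 1 intensity column per strain. Loess was applied to those columns because the log2 ratio rose with brightness, from medians of -0.31, 0.07 and -0.08 in the dimmest of 10 bins of genes to 0.36, 1.25 and 1.46 in the brightest bin for the ppk-, ppx- and double-labelled samples. Median log2 ratios of all genes before normalization were -0.15, 0.46 and 0.50, and changes after loess are relative to these. The counts from the deposited values are given with the other alternatives.

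Log2 ratios of mutant over wild type were computed for each spot with no offset, normalized with loessFit of limma 3.58.1 in R 4.3.3 against mean log2 intensity (span 0.3, 4 iterations) and averaged over the spots of a gene. Genes at or past 2-fold were counted, with no test, since each mutant has 1 sample and no separate cultures are named. The detection floor was set at the 5th percentile of each column, at 139.3 for wild type and 110.0, 140.5 and 123.6 for the ppk-, ppx- and double-labelled samples. Where a called gene was at or under it on 1 side, the fold was computed against the floor, both with and without normalization, and the smaller was given as a bound.

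Genes named in the text were set by a rule fixed before the data were examined. In each mutant, these were the 12 highest and 12 lowest log2 ratios among genes off the floor, the genes of the polyphosphate locus, and the 4 members farthest from 0 of each list whose median lay outside the central 95% of random lists (2.5th to 97.5th percentile). For the differences between mutants, the 6 largest in each direction were named. Genes at the floor in either sample were left out of these, a limit that the rule did not state for differences, and those it removed are named in the text without a fold. The part of the rule that asks for the same sign in both dye orientations could not be used, because orientations are not given apart. The 45 gene lists were also fixed before the data were examined. The median of each was set against 10000 random lists of the same size, matched on mean intensity in 10 bins.

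Overlap between mutants was set against the product of both counts over all genes. The effect of spot noise in the shared wild type was estimated from 100 simulated sets of unchanged mutants with noise from duplicate spots, and by giving each mutant a different wild-type spot. The steps were tested on simulated data made from wild-type spots, with 50 changed genes at each fold in each of 5 runs of 4141 genes. Without a trend along the table, 0% were called at 1.5-fold in any simulated mutant. At 2-fold, which lies on the threshold, 29.2%, 16.8% and 12.4% were called with the duplicate-spot noise of the ppk-, ppx- and double-labelled samples. These shares are lower than an estimate without bias would give there, so the steps returned values under the true change in these simulations. The cause of that was not tested. At 3-fold and at 4-fold 100% were called in each, and no unchanged gene was called. That noise leaves out variation between arrays, labellings and cultures, so it gives no rate of false calls for the real samples. Unchanged simulated genes had median absolute deviations of 0.0774, 0.0824 and 0.0831, against 0.139, 0.395 and 0.314 for all genes observed, in the same order. With the observed trend along the table added, the shares called for the ppx-labelled sample were 2% at 1.5-fold, 37.6% at 2-fold and 93.6% at 3-fold, and for the double-labelled sample 0.4%, 25.6% and 96.8%.

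Alternatives tried were ratios without normalization, median centring alone, a common spread for the arrays, the deposited values, leaving out the dimmest 25% of genes, the median or the brightest spot, other thresholds and random lists not matched on brightness. Chosen after seeing the data were offsets of 50 and 200, each spot alone, leaving out genes near the floor, keeping the spot out of range, and removing the local trend along the table, taken as the median of the other probes within 15 places on each side. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and binomial intervals are exact, from scipy 1.17.1. A shorter version of the raw table with the same values was not used.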

Results

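Transcript levels of Escherichia coli were measured on oligonucleotide arrays in 3 strains altered in inorganic polyphosphate, a chain of phosphate residues that the cell stores. Polyphosphate kinase, encoded by ppk, makes the chain, and exopolyphosphatase, encoded by ppx, shortens it. The samples were labelled ppk mutant (depleted polyphosphate), ppx mutant (accumulated polyphosphate) and ppk-ppx double mutant (no polyphosphate metabolism). Each group held 1 sample and there were no replicates, so no gene was tested and the number of arrays limits the precision. The deposited table gave a raw mean intensity per spot for wild type and for each mutant, with 2 spots for each of 4222 probes, and the same wild-type values stood against all 3 mutants. Values were obtained for 4141 genes. Errors are the SD of the log2 ratio over a gene's spots, which is the error of the array and not of the culture.

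The comparison of each mutant with wild type asks which transcripts differ when polyphosphate is depleted, when it accumulates and when both enzymes are missing. Log2 ratios are given as mutant over wild type, the opposite direction to the deposited value table, which holds wild type over mutant. Gene symbols are those of the deposited table with their ECK codes, and current names follow in parentheses where they differ. A gene is called higher or lower at 2-fold or more after loess normalization. The probes of the deleted genes went against the labels. The ppk probe (ECK2497) had a log2 ratio of -0.10 ± 0.14 in the sample labelled ppk mutant, -0.30 ± 0.08 in the sample labelled ppx mutant and 0.02 ± 0.16 in the sample labelled double mutant. Its intensity was 524 in wild type and 430, 519 and 647 in those samples, in the same order, and the ratio in the double-labelled sample turned to -0.22 with the local trend along the table removed. The ppx probe (ECK2498) gave 0.66 ± 0.01, 0.53 ± 0.05 and 0.48 ± 0.08, and its intensity was 5111 in wild type, 12690 in the ppk-labelled sample, 26150 in the ppx-labelled sample and 25780 in the double-labelled sample. The extent of each deletion and the position of the probes are not given in the sources used here, and a probe outside the deleted part checks nothing. Neighbours of the locus stayed within 2-fold in every sample. These were the purine synthesis genes purN (ECK2496) and purM (ECK2495), and yfgF (pdeF, ECK2499) and yfgG (ECK2500). The value farthest from 0 among them was -0.63 ± 0.10 for purM in the ppx-labelled sample.

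In the sample labelled ppk mutant, rpe (ECK3373), which encodes ribulose-5-phosphate epimerase of the pentose phosphate pathway, was 2.24-fold higher than in wild type (log2 1.16 ± 0.03). The acetyl-CoA acetyltransferase gene atoB (ECK2217), of short-chain fatty acid breakdown, was 2.17-fold higher (1.12 ± 0.02). The flagellar rod gene flgG (ECK1063) was 2.66-fold lower (-1.41 ± 0.02), and hdeB (ECK3493), which encodes a periplasmic acid-resistance protein, was 2.07-fold lower (-1.05 ± 0.18). These 4 genes, 2 in each direction, were all that reached 2-fold, 0.0966% of those measured. Next among the highest were ybaA (ECK0450) at 1.99-fold, nagE (ECK0667) of N-acetylglucosamine uptake at 1.83-fold, the cysteine exporter gene eamA (ECK1526) at 1.82-fold and the predicted diguanylate cyclase gene ycdT (dgcT, ECK1015) at 1.77-fold. The remaining named genes on that side, ygaT (glaH), yoaH, ypdC, ycfN (thiK), yjiR and yhdV, lay between 1.76-fold and 1.69-fold above wild type. All genes named on that side except yoaH were also above wild type in the other samples. Log2 ratios in the ppx- and double-labelled samples were 1.57 and 0.69 for rpe, 0.80 and 0.94 for atoB, and 0.91 and 0.88 for ybaA. They were -0.21 and 0.01 for yoaH. A wild-type value that was too low could alone raise a gene in every sample. The rises shared by all samples thus cannot be assigned to loss of ppk. Below wild type, ycbQ (elfA, ECK0929), a fimbrial gene, stood at 1.68-fold and ymgA (ECK1152) at 1.53-fold. The other named genes on the lower side were yedX (hiuH), the murein transglycosylase gene slt, ykfA, ycgZ, yccJ, yaiW, the regulator gene leuO and yjiX, between 1.51-fold and 1.42-fold below wild type. On this side all but hdeB, ymgA and yccJ were below wild type in every sample. Apart from yoaH, flgG, hdeB, ycbQ and yccJ, wild-type intensities of the genes named here ran from 2920 (nagE) to 6146 (slt). The median of wild-type spots was 888.1. The highest was 7354, against 15890, 36940 and 35930 in the ppk-, ppx- and double-labelled samples. Whether a brightness trend left over after loess accounts for part of these values was not tested.

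Genes of the flagellum had a median log2 ratio of -0.05 in the ppk-labelled sample, at percentile 1.99 of random lists matched on brightness. Of 41 members, 17 were above 0 and flgG alone was past 2-fold. The sigma factor gene fliA, near the detection floor in the mutant, had -0.50 ± 0.05, fliS had -0.34 ± 0.03 and the master regulator gene flhC had -0.23 ± 0.03. Tricarboxylic acid cycle genes had a median of 0.08, at percentile 99.2, with 15 of 20 members above 0 and none past 2-fold. The highest were sucB at 1.61-fold, sdhC at 1.58-fold, the citrate synthase gene gltA at 1.56-fold and sucC at 1.35-fold. Wild-type intensities of sucB, sdhC and gltA were 156.5, 141.4 and 191.8, not far above the floor of 139.3. With the local trend along the table removed, the flagellar list moved inside the range of random lists, while the cycle genes were at percentile 99.8. An offset of 200 on the intensities ended the calls of flgG, at -0.85, and hdeB, at -0.54, which was also at -0.85 with an offset of 50 and -0.92 with the second spot alone. Without loess normalization 27 genes were higher and 2 lower, or 56 and 2 with median centring alone.

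In the sample labelled ppx mutant, yrbK (lptC, ECK3188), a gene of lipopolysaccharide transport, was 6.58-fold higher (log2 2.72 ± 0.14) and the mannitol uptake gene mtlA (ECK3588) was 5.78-fold higher (2.53 ± 0.15). The acid-resistance gene hdeA (ECK3494) was 5.29-fold higher (2.40 ± 0.10), the serine deaminase gene sdaB (ECK2792) 5.05-fold higher (2.34 ± 0.19) and yrbD (mlaD, ECK3182), of phospholipid transport across the envelope, 4.39-fold higher (2.14 ± 0.14). The aldehyde dehydrogenase gene aldB (ECK3577) was 24.5-fold lower (-4.61 ± 0.16), the predicted dehydratase gene rspA (ECK1576) 10.3-fold lower (-3.37 ± 0.74) and murB (ECK3964), of cell wall precursor synthesis, 4.33-fold lower (-2.11 ± 0.71). The intensity of aldB in this sample was 181.5, close to the floor of 140.5. Together 123 genes reached 2-fold, 90 higher and 33 lower, 2.97% of those measured. Other named genes that rose were yghZ (gpr, ECK2995) at 2.32 ± 0.12, yqcB (truC, ECK2785), of tRNA modification, at 2.18 ± 0.19, the arsenate reductase gene arsC at 2.06 ± 0.49, ybaY at 2.04 ± 0.37, the ribosomal protein gene rplE at 1.99 ± 0.08 and the phosphonate breakdown gene phnL at 1.97 ± 0.30. The 12th, ydaG, had 1.96 ± 3.33, since its spots disagreed, and turned to -0.40 with the brightest spot. Wild-type intensities of hdeA, ybaY and phnL were 174.4, 173.4 and 193.2, not far above the wild-type floor of 139.3. Named genes that fell included yeiM (psuT, ECK2157) at -2.20 ± 0.64, the prophage integrase gene intQ at -2.19 ± 0.41, flgG at -1.94 ± 0.04, ydjH at -1.77 ± 0.17, proQ at -1.65 ± 0.08 and the ribosomal protein gene rpmI at -1.62 ± 0.26. The set closed with yiaY, a dehydrogenase gene next to aldB, at -1.60 ± 0.30, priC at -1.51 ± 0.86 and the glycerol-3-phosphate uptake gene ugpE at -1.39 ± 0.11. Intensities of flgG, yiaY and priC in this sample were 164.2, 148.6 and 151.1, close to the floor of 140.5. With an offset of 200 the calls of yiaY (-0.87), priC (-0.81) and ugpE (-0.94) ended, as did that of ugpE (-0.99) with a common spread of the arrays and that of priC (-0.90) with the brightest spot.

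Of the 33 lower genes of the ppx-labelled sample, 7 had an intensity at or under the detection floor, where the fold is a bound. Among them, the galactoside uptake gene mglA (ECK2142) was at least 14.5-fold lower and glpB (ECK2234), of anaerobic glycerol phosphate oxidation, at least 7.24-fold lower. The prophage gene ydfB was at least 12-fold lower, ynfN at least 10.6-fold and the hydrogenase gene hyfC at least 8.93-fold. The opposite case was mokB (ECK1413), at the floor in wild type and at least 6.62-fold higher. The names in this paragraph other than mglA and glpB were chosen after their values were seen.

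General stress genes of the RpoS regulon had a median log2 ratio of 0.15 in the ppx-labelled sample, at percentile 98.4. Of 46 measured members, 30 were above 0, and yiaG at 1.61 ± 0.15 and yqjD at 1.55 ± 0.26 (0.93 with an offset of 200) were past 2-fold. The osmotically induced genes osmE, at 0.88 ± 0.08, and osmB, at 0.81 ± 0.28, were not. Uptake and use of sugars under CRP-cAMP had a median of -0.16, at percentile 1.92, with 27 of 63 members above 0. In that list mtlA rose, mglA and glpB fell, and the galactoside acetyltransferase gene lacA had 0.91 ± 0.02. Neither list stayed outside the range with the local trend along the table removed, at percentiles 93.3 and 13.1, nor without normalization, at percentiles 96.6 and 31.3.

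Position in the deposited table went along with these values. Of the 12 highest genes of the ppx-labelled sample, 6 lay within 50 table places, and medians of successive stretches of 176 probes ran from -0.45 to 0.47. With the local trend removed, 42 genes were higher and 24 lower, of which 39 and 19 were among those counted above. Without normalization 903 genes were higher and 19 lower, and with median centring alone 351 and 67.

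**Figure D1:**
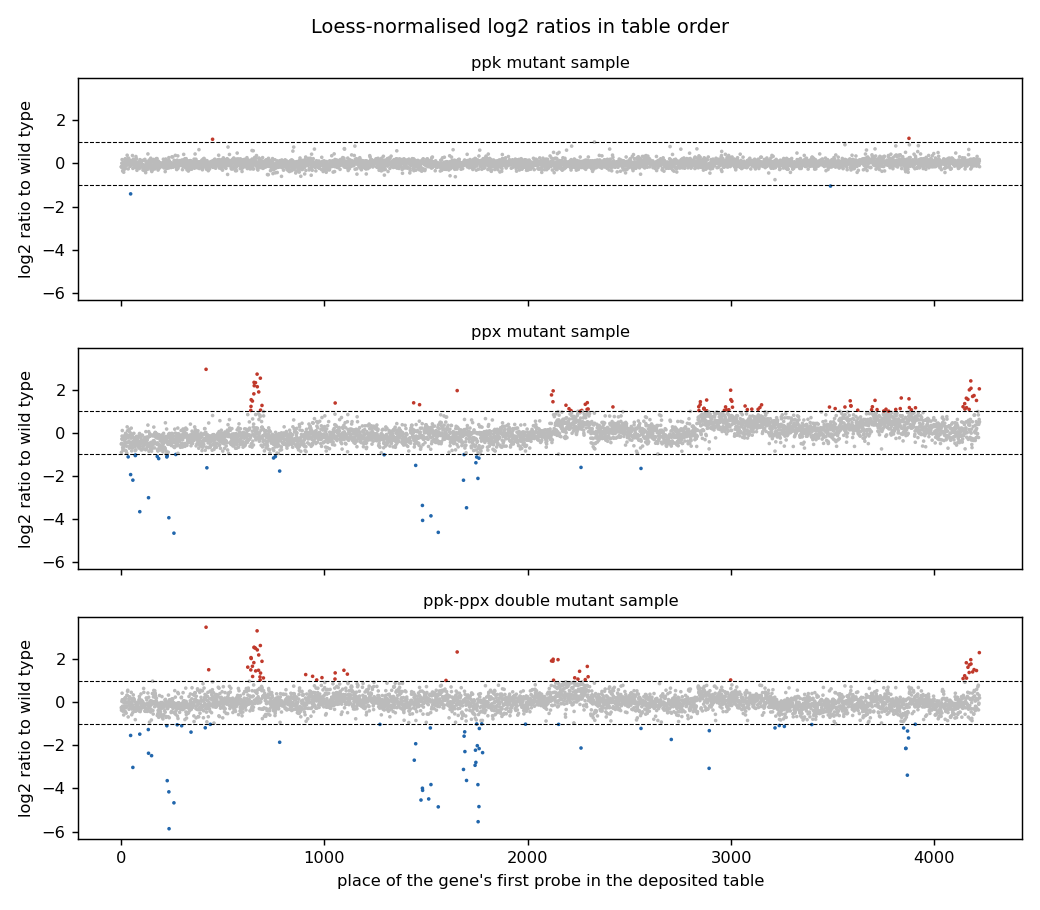
Log2 ratio of mutant over wild type (vertical axis, loess normalized) against the place of the gene's first probe in the deposited table (horizontal axis), 1 panel per mutant sample and 1 point per gene. Red points are at least 2-fold higher and blue points at least 2-fold lower, numbering 2 and 2 in the ppk-labelled sample, 90 and 33 in the ppx-labelled sample and 58 and 62 in the double-labelled sample, with runs of red points in narrow stretches of the table.

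In the sample labelled ppk-ppx double mutant, yrbK (ECK3188) was 9.88-fold higher (log2 3.30 ± 0.18), mtlA (ECK3588) 6.16-fold higher (2.62 ± 0.19) and sdaB (ECK2792) 5.83-fold higher (2.54 ± 0.11). The manganese uptake gene mntH (ECK2387) was 4.18-fold higher (2.06 ± 0.05). The wild-type intensity of mntH was 147.7 and that of ybaY, given below, was 173.4, both close to the wild-type floor of 139.3. Lowest was ydfI (ECK1535), which encodes a predicted sugar acid dehydrogenase, at 58.3-fold lower (-5.86 ± 0.12). The aldehyde dehydrogenase gene aldB was 28.9-fold lower (-4.85 ± 0.40), the GTP-binding protein gene yihA (ECK3857) 28.6-fold lower (-4.84 ± 0.15) and yfdX (ECK2371) 22.4-fold lower (-4.48 ± 0.28). Intensities of ydfI, aldB, yihA and yfdX in this sample were 143.7, 157.7, 127.5 and 177.6, close to the floor of 123.6. With the background unknown, the size of these folds is uncertain. In all, 120 genes reached 2-fold, 58 higher and 62 lower, 2.9% of those measured. Also among the highest were yqcB, with a log2 ratio of 2.53 ± 0.15, yghZ 5.65-fold higher, yrbD at 2.42 ± 0.24, ybaY at 2.29 ± 0.35, yrfF (igaA), an envelope stress regulator gene, at 2.19 ± 0.07, ypdF at 2.02 ± 0.63 and ytfF at 1.99 ± 0.86. The value of ydaG, 2.33 ± 3.32, again came from spots that disagreed and was -0.021 with the brightest spot. Further down were rspA at -3.99 ± 0.36, the prophage gene sieB at -3.64 ± 0.19, the ribosomal RNA methylase gene rsmC (ECK4362) at -3.38 ± 0.11 and yiaD at -2.93 ± 0.48. Of these, rspA, sieB and rsmC had intensities of 152.2, 129.8 and 176.5, also close to the floor. The list ended with the enterobactin esterase gene fes at -2.69 ± 1.18, the hexose phosphate uptake gene uhpT at -2.48 ± 0.67, yiaV at -2.37 ± 0.94 and yggP at -2.34 ± 2.53. The intensity of yiaV was 168.1, close to the floor as well. The gene yggP had 4 spots from 2 probes, which were not both past 2-fold in the same direction, and its brightest spot gave 0.0053.

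Of the 62 lower genes of the double-labelled sample, 21 were at or under the detection floor. The fold was at least 33.3 for yijD (ECK3956), 16.5 for mglA, 15.5 for the heat-inducible gene hslJ, 10.2 for murB and 4.96 for ugpE. Of the 21, 5 were also lower at the floor in the ppx-labelled sample, namely glpB, hyfC, mglA, ydfB and ynfN. From the floor in wild type, mokB was at least 9.57-fold higher. Of the names in this paragraph, yijD, hslJ, hyfC, ydfB, ynfN and mokB were chosen after their values were seen.

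Fatty acid synthesis genes had a median log2 ratio of -0.20 in the double-labelled sample, at percentile 1.77, and 5 of 18 members were above 0. None was past 2-fold. The members farthest from 0 were fabF at -0.50 ± 0.16, fabH at -0.40 ± 0.14, the acetyl-CoA carboxylase gene accD at -0.33 ± 0.03 and fabI at -0.31 ± 0.08. With the local trend along the table removed the list was at percentile 1.11, but without normalization it was inside the range, at percentile 11.4. Over the 45 lists, 2, 2 and 1 lay outside the central 95% of random lists in the ppk-, ppx- and double-labelled samples, where 2.25 per sample would be outside by chance.

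Of the 12 highest genes of the double-labelled sample, 9 lay within 50 table places. With the local trend removed 44 genes were higher and 56 lower, of which 44 and 50 were among those counted above. Without normalization 991 were higher and 49 lower, and with median centring alone 297 and 132.

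**Figure D2:**
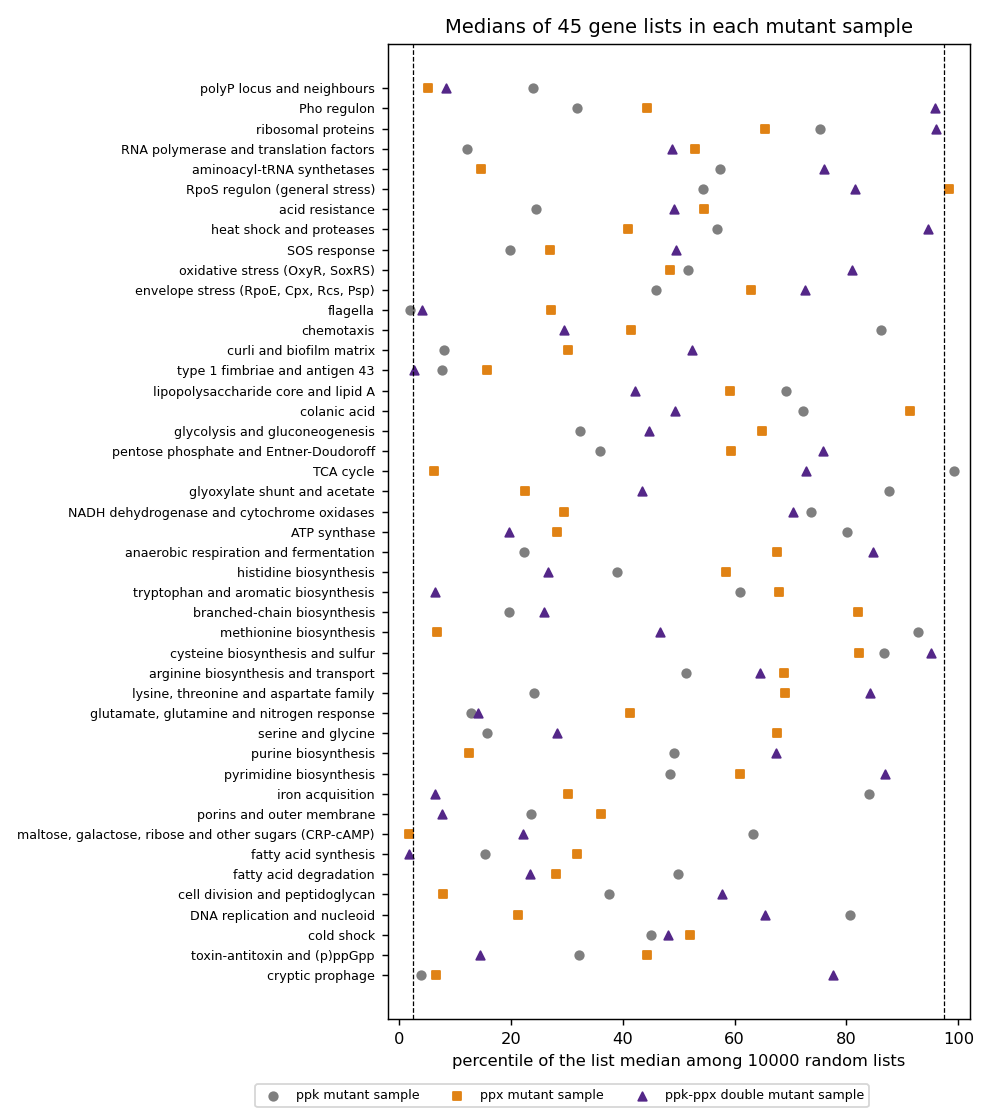
Percentile of the median log2 ratio of each of 45 gene lists among 10000 random lists of the same size matched on brightness (horizontal axis), with 1 symbol per mutant sample and dashed lines at the limits of the central 95%. Flagella and the tricarboxylic acid cycle lie outside the lines for the ppk-labelled sample, the RpoS regulon and the sugar genes for the ppx-labelled sample and fatty acid synthesis for the double-labelled sample. Of these 5, the cycle and fatty acid lists stay outside with the local trend along the table removed, and the flagella and cycle lists without normalization.

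The differences between mutants ask whether loss of both enzymes looks like loss of either. Of the 123 genes changed in the ppx-labelled sample, 60 were changed the same way in the double-labelled sample and 0 the opposite way. Both samples had 37 genes higher, among them yrbK, mtlA, hdeA, sdaB and rplE, where 1.26 would be shared by chance (the product of both counts over all genes). Both had 23 genes lower, among them aldB, rspA, murB and flgG, where 0.494 would be shared. These chance counts ignore position, while sdaB, yrbK and mtlA lay at table places 654, 669 and 685. Higher probes 7 to 9 places apart were more frequent than in random placings in both samples. Regularly spaced spots may thus account for part of the overlap, which was not tested. With the local trend along the table removed, 31 genes higher and 21 lower were shared. Across genes, which are not independent replicates, the log2 ratios of these samples had a Pearson correlation of 0.645 and a Spearman correlation of 0.551, the highest of the 3 pairs computed. Part of this excess may come from the shared wild-type values. Simulated mutants without any change that shared the wild-type spots gave 0.391, but with a covariance of 0.00278 against 0.158 observed, and giving each mutant a different wild-type spot left a correlation of 0.581 and a covariance of 0.149. Both estimates cover only the noise of duplicate spots. An error common to both wild-type spots, of the array or the culture, would stay in every pair of mutants and was not estimated.

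Of the 4 genes called in the ppk-labelled sample, rpe was also higher and flgG also lower in the ppx-labelled sample, 1 gene in each direction against 0.0435 and 0.0159 by chance (2 higher and 1 lower with the local trend along the table removed), and the correlation across genes was 0.293 (0.421 simulated without change, covariance 0.0234 against 0.00279), or 0.155 with a different wild-type spot for each mutant. With the double-labelled sample it shared flgG, lower, against 0.0299 by chance, and the correlation was 0.146 (0.42 simulated, covariance 0.0121 against 0.00278), or 0.0318 with a covariance of 0.00309 when each mutant was given a different wild-type spot. The flagellar rod gene flgG was the 1 gene past 2-fold in all 3 samples, lower in each, at -1.41, -1.94 and -1.54. All 3 ratios rest on the same wild-type spots, with a mean intensity of 534.1 against 173.2, 164.2 and 205.9 in the mutants. A wild-type value that was too high could alone give this, so they are not 3 separate observations. The chance counts leave out this sharing as well.

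**Figure D3:**
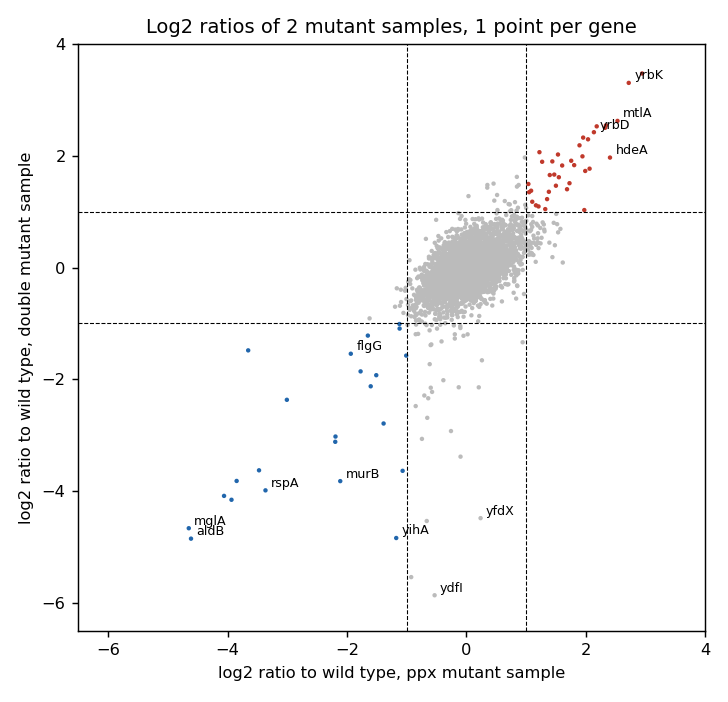
Log2 ratio to wild type in the ppx-labelled sample (horizontal axis) against the double-labelled sample (vertical axis), 1 point per gene, loess normalized, with dashed lines at 2-fold. Red points (37) are higher and blue points (23) lower in both samples, and some genes such as ydfI and yfdX lie far below 0 in the double-labelled sample alone.

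Genes named for the differences between samples were off the detection floor in both samples compared, while the counts include genes at the floor. Subtracting the ppk-labelled from the ppx-labelled sample left 88 genes higher and 36 lower by 2-fold. The highest were yrbK at 2.89, hdeA at 2.66, mtlA at 2.52, sdaB and yrbD at 2.39 and yghZ at 2.29, and the lowest aldB at -4.52, rspA at -3.14, yeiM at -2.26, murB at -2.22, intQ at -1.96 and ydjH at -1.90. For the double-labelled minus the ppk-labelled sample, 62 genes were higher and 66 lower. At the top were yrbK at 3.47, yrbD at 2.68, mtlA at 2.61, sdaB at 2.60, yqcB at 2.51 and yghZ at 2.46. At the bottom were ydfI at -5.66, yihA at -5.19, aldB at -4.76, yfdX at -4.51, rspA at -3.76 and sieB at -3.51.

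Between the double-labelled and the ppx-labelled sample 11 genes were higher in the former and 44 lower. The phosphate-responsive gene phoH (ECK1010) differed by 1.36, from -0.51 ± 0.02 to 0.85 ± 0.23, although neither value was past 2-fold. It was followed by yafZ at 1.24, whose spots disagreed in the double-labelled sample (SD 2.02), the response regulator gene yehT (btsR) at 1.19, the cell envelope gene tolA at 1.13, the formate dehydrogenase gene fdoG at 1.11 and pyrI, of pyrimidine synthesis, at 1.09. Lower in the double-labelled sample were ydfI at -5.33, yfdX at -4.72, yihA at -3.66, rsmC at -3.29, yiaD at -2.67 and sieB at -2.57. By computed value, 5 of the 6 lowest genes of the ppx minus ppk difference were at the floor (mglA, ynfN, hyfC, ydfB and yfdR), as were yijD and mglA for double minus ppk and yijD and hslJ for double minus ppx. Also at the floor were mokB, highest in both differences from ppk, and yfdR, highest in double minus ppx. Set against the sum of both single mutants, the double-labelled sample had 23 genes higher and 85 lower. With the local trend along the table removed the ppx minus ppk difference held 69 genes and the difference from the sum 47, against 124 and 108 before. Double minus ppx then had 6 genes higher and 33 lower, and yehT (0.96), tolA (0.86), fdoG (0.65) and pyrI (0.94) were no longer past 2-fold.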

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

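Chosen after the results were seen were the offsets, each spot alone, leaving out genes near the floor, keeping the spot out of range and removing the local trend; the other alternatives were fixed before. Counts are of genes past the threshold, in the order ppk, ppx, double, ppx minus ppk, double minus ppk, double minus ppx, double minus the sum of both single mutants, and genes shared by ppx and double in 1 direction. The counts reported were 4, 123, 120, 124, 128, 55, 108 and 60. Without normalization they were 29, 922, 1040, 907, 1069, 91, 215 and 636, and with the deposited values 27 (24 higher), 843 (823 higher), 944 (895 higher), 822, 977, 89, 206 and 581. At 1.5-fold they were 34, 683, 470, 550, 500, 473, 737 and 234, at 3-fold 0, 38, 61, 32, 58, 20, 23 and 30, and at 2 robust SD of each array 308, 292, 404, 324, 459, 275, 219 and 146; a lower or higher threshold itself accounts for these. With an offset of 200 they were 2, 61, 73, 52, 71, 26, 50 and 37, since an offset shrinks ratios of dim spots. Median centring alone gave 58, 418 and 429 for the mutants, 195, 102 and 231 for the last 3 differences and 243 shared genes. Scaling to a common spread gave 49 for ppk (35 higher and 14 lower), 51 for ppx and 187 for the difference from the sum, and leaving out the dimmest 25% of genes gave 2 for ppk. Removing the local trend gave 66 for ppx, 69 for ppx minus ppk and 47 for the difference from the sum. Apart from the thresholds and offsets, the cause was not tested.

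The number of gene lists outside the range, reported as 2, 2 and 1 for ppk, ppx and double, became 1 for ppk and 1 for ppx without the dimmest 25%, 1 for ppx with the deposited values, and 1, 1 and 2 with an offset of 200 and also without genes near the floor. It became 1 for ppx and 2 for double with an offset of 50 and with each spot alone, 1 for ppx and 3 for double with the brightest spot, 3 for double with the local trend removed, and 1 for ppk and 2 for double with unmatched random lists. Without normalization it was 2, 2 and 1 again, but the lists were different ones in ppx (flagella, and iron acquisition) and in double (serine and glycine). It was also 2 for ppk and 2 for ppx with the local trend removed, but 1 of the ppk lists (type 1 fimbriae in place of flagella) and both ppx lists (iron acquisition, and cold shock) were different ones. In double, flagella (percentile 0.58) and iron acquisition (2.03) joined fatty acid synthesis with the local trend removed. With unmatched random lists, flagella moved inside the range in ppk (2.6), and type 1 fimbriae (2.47) joined fatty acid synthesis (1.4) in double. For the remaining alternatives the counts do not say which lists lay outside. Named genes past 2-fold kept their direction except ydaG, at -0.40 in ppx and -0.021 in double with the brightest or first spot, and yggP, at 0.0053 in double with the brightest spot, whose spots disagreed; beyond that the cause was not tested. All other counts stayed within 1.5 times the reported ones. Of 109 other values (log2 ratios of named genes, and the correlation of ppx with double), 58 stayed within the SD of the spots with the local trend removed, 43 with an offset of 200, 39 with median centring and 23 without normalization. For 2 spots the median equals the mean and each spot lies within 1 SD of it, so those alternatives say little about named genes.

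Leaving out an array or a dye orientation was not run, because each strain has 1 column, nor was a limma fit or t-test, because there are no replicates; offset 0 was the one used. No paired analysis was possible because each group holds 1 sample. Signal over background is unknown, since no background was given.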

Other observations

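Genes described here without a rule were chosen after their values were seen. In the Pho regulon, which responds to phosphate limitation, median log2 ratios were -0.02, -0.04 and 0.12 in the ppk-, ppx- and double-labelled samples, all within the range of random lists (percentiles 31.8, 44.4 and 95.9). Of 34 members, phnC (1.07) and phnL (1.97) of phosphonate use were higher in the ppx-labelled sample and ugpE (-1.39) lower, though phnC was at 0.62 with the local trend along the table removed. In the double-labelled sample phnL was higher (1.03, or 0.89 with that trend removed), and ugpE was at least 4.96-fold lower. Among 54 ribosomal protein genes, rplE (1.99 and 1.73) and rpsC (1.08 and 1.37) were higher in the ppx- and double-labelled samples (rpsC at 0.82 in the former with that trend removed), and rpmI (-1.62) was lower in the ppx-labelled sample, while the list medians were inside the range of random lists in all 3 samples. Cryptic prophage genes had 1 higher and 4 lower members of 77 in the ppx-labelled sample and 0 higher and 5 lower in the double-labelled sample, including intQ, sieB, ydfB and yfdR, with list medians inside the range of random lists, and sieB was at -0.69 in the ppx-labelled sample with that trend removed. Among acid resistance genes, the neighbours hdeA and hdeB, which form an operon, parted in the ppx-labelled sample, at 2.40 ± 0.10 and 0.16 ± 0.41. They also parted in the double-labelled sample, at 1.97 ± 0.17 and -0.59 ± 0.04, and in the ppk-labelled sample, at -0.25 ± 0.04 and -1.05 ± 0.18.

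The tests below were chosen only after the result was seen, except the common spread and the threshold at 2 robust SD. The first pattern is the larger number of genes past 2-fold in the ppx- and double-labelled samples than in the ppk-labelled sample, such as yrbK, mtlA and aldB. All ratios had a wider spread in those samples (median absolute deviation 0.395 for ppx and 0.314 for double against 0.139 for ppk), and counts relative to each array's own spread, which take that out by construction, were 49 for ppk, 51 for ppx and 99 for double after scaling to a common spread, and 308, 292 and 404 past 2 robust SD. With the local trend along the table removed, 66 and 100 genes still passed against 4 in the ppk-labelled sample, which argues against that trend as the whole cause. The share of genes within 20 bp of a changed gene with a log2 ratio of its sign was 37.5% (18.8 to 59.4) and 41.4% (23.5 to 61.1) for higher genes of ppx and double. For lower genes it was 60.0% (36.1 to 80.9) in ppx and 41.5% (26.3 to 57.9) in double. Changes of whole transcription units (set at 75% or more) stay open, because log2 ratios of 2 probes of 1 gene hardly agreed in these samples. Their correlations were 0.132 and 0.0385 for ppx and double with that trend removed, inside the random limits, so the share of neighbouring genes cannot decide, even where the names are right. Regularly spaced spots may account for part, since pairs of changed probes 7 to 9 places apart numbered 44 for higher genes of the ppx-labelled sample, 51 for higher and 20 for lower genes of the double-labelled sample, where the central 95% of random placings reached up to 29, 27 and 18, while the 4 pairs of lower genes of the ppx-labelled sample (upper limit 7) cannot be told apart from chance. Separate hybridisation or scanning and a real effect of the mutations both stay open and cannot be told apart. The correlation of 0.994 between wild type and the ppk-labelled sample is what either would give. Lack of polyphosphate alone would make the double-labelled sample resemble the ppk-labelled sample, since by the labels both lack the kinase. Instead its log2 ratios correlated at 0.146 with those of the ppk-labelled sample and at 0.645 with those of the ppx-labelled sample. With 1 sample per strain, these values do not decide between the causes.

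The second pattern is that the probes of ppk and ppx were not lower in the samples labelled as lacking them. The lowest log2 ratio over the 3 mutants was -0.30 for the ppk probe and 0.48 for the ppx probe. A swap of labels among the mutants would leave a low value in some column only if the probes lie in the deleted parts, so with their positions not given it cannot be told apart from correct labels. Probes outside the deleted parts could give these values, with the ppx probe at percentile 99.8 of brightness in the ppx-labelled sample. This cannot be told apart from an intact gene, because the deleted parts are not given in the sources used here. No biological explanation was tested.

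The third pattern is that the brightness of wild-type spots did not follow what the names are known to encode, with ribosomal protein genes, abundant in growing cells, at percentile 49.7. Names moved along the table by a constant number of places are argued against as the whole cause of this, since the best of all shifts put these genes at percentile 73.4, while the best shift of random lists gave 69.8 to 77.1. Where brightness does not follow abundance, this test could not find a shift. All names set at random are argued against as well, since probes sharing a name correlated at 0.432 in wild type, above the upper limit of 0.215 for random pairs, although their log2 ratios did so in the ppk-labelled sample alone (0.375, against 0.107 for ppx and 0.0877 for double, inside the random limits). Brightness that depends on the probe or its labelling more than on transcript abundance may remain, as genes within 20 bp of each other correlated at 0.0639, but it cannot be told apart from names set wrongly in part, which would lower that value too. No biological explanation was tested, and gene names carry this doubt throughout.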
